A study of Mus musculus with 10 samples.

How the data were processed

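Gene expression was measured by poly-A RNA sequencing (BGISEQ-500) of mouse intestinal tissue in 10 libraries: untreated WT (3), untreated TG (3), WT after DSS (2) and TG after DSS (2), with groups taken from the labels. The authors' notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mm10 genome, without stating the role or order of each tool. The authors deposited 1 table per library, with an Entrez gene identifier, a symbol, an expected count, an FPKM value and a gene length for each gene. Per the file headers the count column holds expected counts, the value RSEM assigns to a gene. The deposited FPKM values are fragments per kilobase scaled to library size, and the deposited gene length is in bases. It was checked that FPKM times length divided by expected count is nearly constant within a library. A gene is listed in a table only where its FPKM reaches 0.01 after rounding, so a gene missing from a library was set to 0. In all, 19456 genes occur in at least 1 library and 14600 in every library. Of 26 symbols missing or turned into dates, 25 were restored from the gene identifier. Coordinates and gene names come from the RefSeq annotation of GRCm38.p6, which held 19399 of the identifiers. The tables carry a human ITGB6 entry, which was kept as its own gene.

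Library depth, as the sum of expected counts, was 16465983, 16090249 and 15393859 for untreated WT, 17304237, 16626453 and 16488388 for untreated TG, 17374911 and 17976069 for WT after DSS, and 17702754 and 18284704 for TG after DSS. The 10 most abundant genes held 6.21 to 8.59% of a library. The first 2 principal components of log2 CPM held 43.7 and 19.5% of the variance. Same-group libraries were checked pair by pair against counting error and none was a duplicate of another (chi-square per gene 9.99 to 65.15 over 8 pairs).

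Expected counts were rounded, scaled by TMM and filtered with filterByExpr (count minimum 10, total minimum 15), which kept 14072 genes. A quasi-likelihood model with 1 mean per group was fitted to all 10 libraries in edgeR 4.0.16 under R 4.3.3 (6 residual degrees of freedom, biological coefficient of variation 0.171). The 5 contrasts were TG against WT untreated, TG against WT after DSS, DSS against untreated in WT, DSS against untreated in TG, and the genotype by DSS interaction. A gene passed at Benjamini-Hochberg adjusted p under 0.05, and standard errors are the log2 fold change divided by the root of the F statistic. Folds of S100a8, S100a9 and human ITGB6 between groups with few counts are ratios of pooled counts with 95% counting intervals, or, where a group had 0 counts, lower bounds against a floor of 3 counts over the group. These intervals and floors cover counting error only.

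Gene lists were written before the data were examined. Of 43 lists, 42 had at least 5 measured genes and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). The pancreatic acinar cells list had too few measured genes and was not tested. Each list was tested again with an estimated correlation and with fry. Counts within a list use adjustment over all genes unless said to be over the list alone. The preset correlation gave 18, 15, 21, 24 and 18 passing lists in the 5 contrasts in the order above, and the estimated correlation 1, 0, 0, 0 and 1. By camera with an estimated correlation, 2, 3, 5, 5 and 9 lists were under 0.05 before adjustment, and lists were not tested with DESeq2. A list given over to sex-linked genes was tested but its result is given only through single genes.

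Named genes were chosen by a rule fixed before the data were examined. They are, per contrast, Itgb6, the 10 largest passing rises and falls with a mean of at least 1 CPM and no overlap between the libraries of the groups compared, and up to 4 passing members of a passing list. The genes Itgb6, Itgav, Tgfb1, Col1a1, Col3a1, Acta2 and Fn1 were followed in every contrast. The report leaves some of these out, preferring genes that pass in all 10 fits without a library. Ptprc, Krt8, Myh11, Xist, Kdm5d, Ddx3y and Uty were looked at as markers of tissue and sex after the values were seen.

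Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors, upper quartile scaling, total count scaling, no low-count filter, at least 1 CPM in 5 libraries, fits of only the groups compared, the replicate number as a block, limma on log2 FPKM with a pseudocount of 1 or 0.1 (FPKM of at least 1 in 2 libraries) or without a filter, and robust empirical Bayes. Fits without each of the 10 libraries were also fixed then. Leaving out genes of the X and Y chromosomes was added after the data were seen. The edgeR gene test was run on simulated counts with 200 changed genes per contrast. Genes were drawn independently around a mean shared by all groups, with mean and spread estimated from these libraries. The gene test recovered 77.3, 43.9, 57.6, 50.8 and 14.9% of 2-fold changes in the 5 contrasts, with 6.2, 8.5, 3.5, 5.1 and 6.2% of passing genes false and 0 wrong signs. The simulation held no correlation between genes and no deviating library, so these rates do not cover the list tests or such departures. Replicate numbers were checked for pairing across groups (2 of 13 same-number pairs correlated above 0.1). Both were WT DSS with TG DSS, at 0.21. In groups of 2 the deviations mirror each other, so these 2 pairs hold 1 value and pairing cannot be excluded. The labels state no pairing, and samples were not paired. With groups of 2 or 3 libraries no library was removed as deviating.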

Results

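The 10 libraries were intestinal tissue of C57BL/6 mice, wild type (WT) or transgenic for ITGB6 (TG). They came from untreated mice (3 WT and 3 TG) or from mice given 2.5% oral dextran sulfate sodium (DSS, 2 WT and 2 TG). Each held 15393859 to 18284704 deposited expected counts over 16391 to 16949 listed genes. Epithelial transcripts dominated: Krt8, an epithelial keratin, stood at 5432 to 8801 CPM (counts scaled to library depth), while the smooth muscle genes Myh11 and Acta2 stayed below 1.3 CPM. The labels do not state whether the libraries come from separate animals, so p-values measure the spread between these samples. The sex-linked genes split the libraries exactly by treatment. Xist, transcribed from the inactive X, read 0 to 0.42 CPM in all 6 untreated libraries and 307 to 739 CPM in all 4 DSS libraries. Kdm5d, a Y-linked demethylase gene, read 26.6 to 44.2 CPM in the untreated libraries and 0 CPM in the DSS libraries. The Y-linked genes were lower in TG untreated 1 than in the other untreated TG libraries, at 14.2 CPM against 43.7 and 43.8 for Ddx3y and 7.63 CPM against 23.6 and 19.4 for Uty, with Xist at 0. Every comparison of DSS with untreated tissue is therefore also a comparison of females with males.

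**Figure D1:**
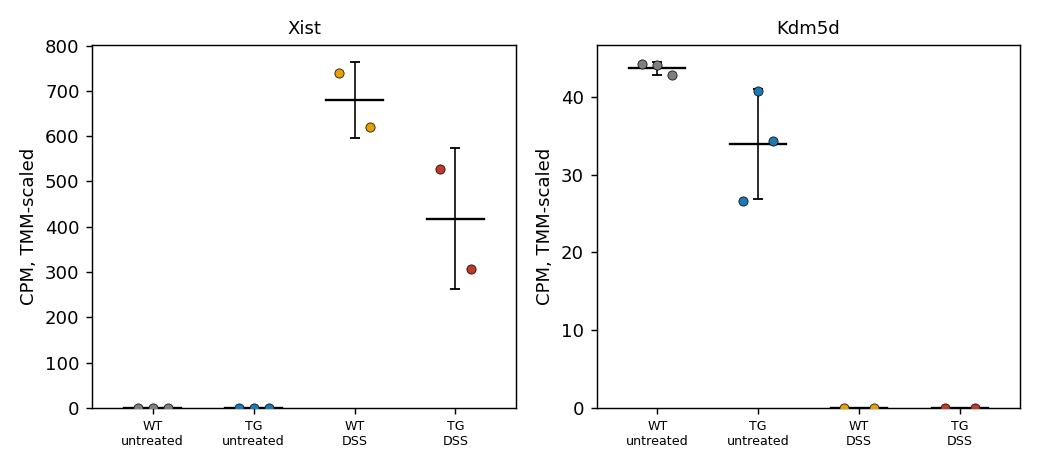
Xist and Kdm5d in CPM (vertical axis), 1 point per library in each of the 4 groups (n = 3, 3, 2 and 2). Xist reaches 307 to 739 CPM only after DSS and Kdm5d 26.6 to 44.2 CPM only in untreated tissue.

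The deposited tables carry a separate entry for human ITGB6, the transgene, beside mouse Itgb6, the subunit of the TGF-beta-activating integrin alpha v beta 6. The human entry read 3800 ± 148 CPM (mean ± SD, n = 3) in untreated TG and 2330 ± 178 CPM (n = 2) in DSS-treated TG. WT libraries read 0.12 ± 0.00294 CPM untreated (6 counts in all) and 0.922 ± 0.301 CPM after DSS (33 counts). The ratio of TG to WT was 31700 in untreated tissue (95% counting interval 14600 to 86400) and 2500 after DSS (1780 to 3630). Within TG the transgene fell by 0.71 on the log2 scale with DSS (SE 0.13, adjusted p = 0.0116). That call ended without TG DSS 1 (adjusted p = 0.0604) or TG DSS 2 (0.145). Mouse Itgb6 (gene ID 16420, chromosome 2, 60598292 to 60722603, GRCm38) did not follow the transgene. It read 21.4 ± 1.23 CPM in untreated WT and 18.8 ± 2.17 in untreated TG (log2 fold change -0.19 ± 0.14, SE, adjusted p = 0.449). After DSS it read 33.6 ± 6.72 in WT and 29.1 ± 1.6 in TG (log2 fold change -0.21 ± 0.17, adjusted p = 0.693), and the sign turned to 0.01 without WT DSS 1. How reads common to the human and mouse sequences were divided between the 2 entries is not known, so small differences in Itgb6 are uncertain.

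**Figure D2:**
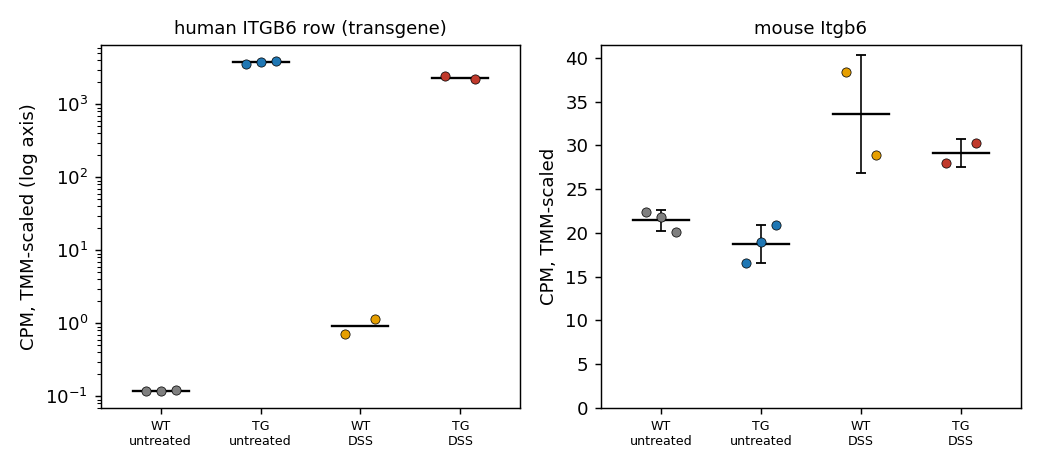
Human ITGB6 (logarithmic axis) and mouse Itgb6 in CPM (vertical axes), 1 point per library with bars at the group mean (n = 3, 3, 2 and 2) and error bars of 1 SD for Itgb6. Human ITGB6 averages 3800 CPM in untreated TG, and Itgb6 stays between group means of 18.8 and 33.6 CPM.

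In untreated tissue the question was how TG differed from WT. Fn1, which encodes the matrix protein fibronectin (ID 14268, chromosome 1, 71585473 to 71653280), rose 6.95-fold in TG (log2 2.80 ± 0.30, SE), from 5.57 ± 1.95 CPM (SD, n = 3) to 38.7 ± 12.9 CPM (n = 3). Retnlb, a bactericidal goblet cell protein (ID 57263, chromosome 16, 48816856 to 48818892), rose 6.70-fold (log2 2.74 ± 0.25), from 162 ± 53.4 to 1083 ± 217 CPM. Pla2g4c, a cytosolic phospholipase A2 (ID 232889, chromosome 7, 13311507 to 13360674), rose 9.27-fold (log2 3.21 ± 0.23), from 36.3 ± 12.8 to 337 ± 46.7 CPM. Mt2, a metal-binding metallothionein (ID 17750, chromosome 8, 94172618 to 94173567), fell by 2.71 on the log2 scale (SE 0.15), from 113 ± 4.12 to 17.3 ± 3.55 CPM. Cyp4b1, a cytochrome P450 (ID 13120, chromosome 4, 115624698 to 115647721), fell by 3.08 (SE 0.28), from 51.4 ± 16.1 to 6.05 ± 1.37 CPM. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00203 for Fn1, 0.000956 for Retnlb, 0.00029 for Pla2g4c, 2.44e-05 for Mt2 and 0.000956 for Cyp4b1. For each of the 5, all 3 TG libraries lay beyond all 3 WT libraries, which the naming rule required of the largest rises and falls. Other large rises were Pnliprp2, a pancreatic lipase relative (9.32-fold), and Bhlha15, a transcription factor of secretory cells (6.40-fold). Other large falls were the kallikrein gene Klk15 (5.59-fold lower), the ion pump regulator Fxyd4 (5.39-fold lower) and Cubn, the vitamin B12 receptor (3.72-fold lower).

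Several gene groups shifted in TG. Of 26 measured interferon response genes, 15 were higher in TG (18 when adjusted over the list alone), with a median log2 fold change of 1.34 (camera adjusted p = 5.67e-12, adjusted p = 0.38 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, rose 4.23-fold (log2 2.08 ± 0.24, adjusted p = 0.00322), and Bst2, which tethers enveloped viruses, rose 3.41-fold (log2 1.77 ± 0.17, adjusted p = 0.00119). The interferon response count was 4, 6 and 2 without WT untreated 1, 2 and 3, and 6 and 8 without TG untreated 2 and 3. Of 17 antimicrobial and mucosal defence genes, 8 were higher (over the list alone 10 higher and 1 lower), with a median of 1.65, or 1.43 with genes at 0 counts in a group placed at their bound. The antimicrobial and mucosal defence median was 0.70 on log2 FPKM with a pseudocount of 1. The list passed (camera adjusted p = 3.69e-09, adjusted p = 0.0334 with an estimated correlation), and it was tested only without the bound. The count was 5 without WT untreated 2 and 2 without WT untreated 3. Duoxa2, the maturation factor of the epithelial oxidase DUOX2, rose 3.14-fold (log2 1.65 ± 0.22, adjusted p = 0.00585).

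Of 21 unfolded protein response genes, 12 were higher (13 over the list alone), with a median of 0.74 (camera adjusted p = 4.12e-12, adjusted p = 0.0763 with an estimated correlation). Creld2, an endoplasmic reticulum stress protein (ID 76737, chromosome 15, 88819646 to 88826681), rose 2.51-fold (log2 1.33 ± 0.12, adjusted p = 0.000956), from 22.2 ± 2.37 to 55.7 ± 1.24 CPM. Hyou1, a chaperone, rose 2.31-fold (log2 1.21 ± 0.12), Manf, a secreted stress factor, 2.23-fold (1.16 ± 0.11), and Sdf2l1, a chaperone cofactor, 2.34-fold (1.23 ± 0.13). The unfolded protein response count was 6 without WT untreated 2, 5 without WT untreated 3 and 7 without TG untreated 2. Of 15 goblet cells markers, 6 were higher (9 over the list alone), with a median of 0.57 (camera adjusted p = 3.4e-07, adjusted p = 0.38 with an estimated correlation). Spink4, a protease inhibitor of goblet cells, rose 3.16-fold (log2 1.66 ± 0.19, adjusted p = 0.00322). The goblet cells count was 1 without WT untreated 2 or 3, and 2 without TG untreated 2. Of 5 measured Paneth cells markers, Pnliprp2 among them, 3 were higher at unadjusted p under 0.05 by edgeR. As a group they shifted up (median 1.95, camera adjusted p = 0.00261), but did not pass with an estimated correlation. Their median difference from untreated WT was 2.24, 1.96 and 1.98 in TG untreated 1, 2 and 3. The Paneth cells call ended in 2 of the 10 fits without a library.

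Of 36 collagens and matrix proteins, 12 were higher (over the list alone 14 higher and 1 lower), with a median of 1 (camera adjusted p = 2.05e-07, adjusted p = 0.38 with an estimated correlation). The collagens and matrix proteins median was 0.20 on unfiltered log2 FPKM with a pseudocount of 1. Col1a1, a fibrillar collagen (ID 12842, chromosome 11, 94936224 to 94953042), rose 3.46-fold (log2 1.79 ± 0.37, adjusted p = 0.0289). Col3a1 (ID 12825, chromosome 1, 45311538 to 45349706) rose 3.94-fold (log2 1.98 ± 0.42, adjusted p = 0.031). Without WT untreated 1, WT untreated 2, WT untreated 3, TG untreated 2 or TG untreated 3, adjusted p of Col1a1 was 0.117, 0.131, 0.05, 0.0956 and 0.0787, and that of Col3a1 0.119, 0.129, 0.0737, 0.114 and 0.0808. The Col3a1 call also ended without TG DSS 1 (adjusted p = 0.0531) or TG DSS 2 (0.0532). The collagens and matrix proteins count was 3, 1 and 2 without WT untreated 1, 2 and 3, 1 without TG untreated 2 or 3, and 7 without TG DSS 1 or 2. The 16 fibroblasts markers did not pass as a group (median 0.40, camera adjusted p = 0.557) but did without TG untreated 1 (0.0314), and the 6 endothelium markers did not pass (median 0.06, camera adjusted p = 0.739). The fibroblasts median was 0.69 without WT untreated 2, 0.17 without TG untreated 2 and 0.14 without TG untreated 3. The endothelium median took either sign, from -0.05 without WT DSS 1 to 0.16 without TG untreated 1. Under other scalings the lowest fibroblasts median was -0.01 and the lowest endothelium median -0.35. Differences from untreated WT in TG untreated 1, 2 and 3 were -0.51, 0.69 and 0.37 for fibroblasts and 0.34, 1.26 and 1.10 for collagens. The order of the libraries was the same, but in TG untreated 1 fibroblasts lay below untreated WT and collagens above. Fn1 did not follow this order, at 45.8, 23.9 and 46.6 CPM.

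Other non-epithelial groups passed in untreated TG with few or no single genes. Of 15 T cells markers, 0 passed singly by the edgeR quasi-likelihood test (6 lower at unadjusted p under 0.05, 2 lower by DESeq2, 0 over the list alone), and 1 was lower without TG untreated 3. As a group the T cells markers shifted down (median -0.74, 0 of 15 above 0, camera adjusted p = 0.000404, adjusted p = 0.695 with an estimated correlation), with a median of -0.36 without WT untreated 2, -0.47 without TG untreated 1 and -1.22 without TG untreated 3. Of 12 MHC class II presentation genes, 1, H2-DMb1, was lower (over the list alone 1 higher and 5 lower), and 3 lay above 0. The MHC class II presentation lower count was 0 by edgeR without TG untreated 2 (5 lower at unadjusted p under 0.05, adjusted p = 0.0765 for H2-DMb1) or TG untreated 3 (7 lower, 0.065), while DESeq2 was not run without those libraries, and 1 gene was also higher without TG untreated 1. As a group they shifted down (median -1.57, camera adjusted p = 0.0219, adjusted p = 0.726 with an estimated correlation), with a median of -0.53 without WT untreated 2 and -1.01 on unfiltered log2 FPKM with a pseudocount of 1. The MHC class II presentation call ended without TG untreated 1 (0.286), TG untreated 2 (0.0977), WT DSS 1 (0.0562), WT DSS 2 (0.0559), TG DSS 1 (0.0569) or TG DSS 2 (0.0569). Of 6 erythrocytes markers, 0 passed singly by edgeR (6 higher at unadjusted p under 0.05, 1 higher by DESeq2, 6 higher over the list alone), and 2 were higher without TG DSS 1 or TG DSS 2. As a group the erythrocytes markers shifted up (median 1.1, camera adjusted p = 0.00143, adjusted p = 0.42 with an estimated correlation). TG untreated 1 stood apart widely. Its rank correlation with the other untreated TG libraries was 0.973 and 0.975, against 0.993 between those libraries, and its second principal component score was -59.7 against -10.1 and -5.7. Ptprc, the pan-leukocyte antigen CD45, read 8.94 CPM there against 56.9 and 79.5 CPM in the others. TG untreated 3 stood apart in B cells markers, with a median difference of 2.91 against -0.95 and -0.04.

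Absorptive and clock genes ran the other way. Of 24 colonocytes markers, 4 were lower (10 over the list alone), with a median of -0.37 (camera adjusted p = 0.000479, adjusted p = 0.38 with an estimated correlation). Atp12a, the colonic proton pump, fell by 1.37 on the log2 scale (SE 0.14, adjusted p = 0.00159). The colonocytes count was 1 without WT untreated 2, and 2 without WT untreated 3, TG untreated 2 or TG untreated 3. Of 16 circadian clock genes, 4 were lower (over the list alone 1 higher and 6 lower), with a median of -0.31 (camera adjusted p = 0.0147, adjusted p = 0.38 with an estimated correlation), and the list call ended without TG untreated 2 (0.0673). Per3, a period gene, fell by 1.06 (SE 0.14, adjusted p = 0.00553), and the repressor gene Cry2 fell by 0.81 (SE 0.12, adjusted p = 0.0106). The circadian clock count was 2 without WT untreated 1, WT untreated 2, TG untreated 2 or TG untreated 3. In all, 520 of 14072 tested genes differed (318 higher, 202 lower). The split was 235 and 382 under total count scaling, and 225 and 331, 218 and 312, and 169 and 272 in the 3 FPKM fits. The number was 132, 91 and 58 without WT untreated 1, 2 and 3, and 136 and 247 without TG untreated 2 and 3, while 24 of the 65 named genes passed in every fit.

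In WT tissue, inflammatory and epithelial genes differed widely between DSS and untreated libraries, with sex changing alongside. Slpi, a secreted antiprotease (ID 20568, chromosome 2, 164354070 to 164356507), rose 26.8-fold (log2 4.75 ± 0.31, SE, adjusted p = 3.63e-05), from 3.38 ± 0.951 CPM (SD, n = 3) to 91.1 ± 23.5 CPM (n = 2). Il1b, the cytokine interleukin 1 beta (ID 16176, chromosome 2, 129364569 to 129371164), rose 26.6-fold (log2 4.74 ± 0.37, adjusted p = 7.23e-05), from 0.658 ± 0.258 to 17.7 ± 4.16 CPM. Clca4b, an epithelial chloride channel regulator, rose 90.2-fold (log2 6.50 ± 0.45, adjusted p = 3.94e-05), from 11 ± 3.89 to 993 ± 442 CPM. Tef, a clock output transcription factor (ID 21685, chromosome 15, 81802673 to 81826863), fell by 3.09 (SE 0.14, adjusted p = 5.84e-06), from 197 ± 3.9 to 23.0 ± 3.85 CPM. Dbp, a related clock output factor (ID 13170, chromosome 7, 45705100 to 45710203), fell by 4.72 (SE 0.30, adjusted p = 2.85e-05), from 104 ± 17.3 to 3.96 ± 0.411 CPM. In each of these genes both DSS libraries lay beyond all 3 untreated libraries, a condition for naming among the largest rises and falls. Collection times are not given, so for Tef and Dbp time of day cannot be told apart from DSS. The calprotectin subunit genes were barely counted in untreated WT. S100a8 rose at least 89.5-fold against a floor of 3 counts over the group, and S100a9 rose 474-fold by pooled counts (95% interval 84.4 to 18800).

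Of 11 neutrophils markers, 11 were higher (median 4.35, or 4.31 with absent genes at their bound, camera adjusted p = 1.17e-11, adjusted p = 0.0634 with an estimated correlation). The neutrophils median was 1.5 on log2 FPKM with a pseudocount of 1 (7 genes) and 0.94 without a filter. Ptprc was lower after DSS, at 19.2 ± 4.45 CPM (n = 2) against 80.9 ± 28.6 CPM (n = 3). The neutrophils markers therefore do not by themselves show a larger share of leukocytes. Ltf, neutrophil lactoferrin, rose 25.6-fold (log2 4.68 ± 0.48), and its log2 value was 5.63 without WT untreated 2. Of 28 inflammatory cytokines and chemokines, 20 were higher and 2 lower (over the list alone 23 and 3), with a median of 2.28 (camera adjusted p = 2.95e-11, adjusted p = 0.195 with an estimated correlation), or 1.28 (21 genes) and 0.97 in those FPKM fits. Tnf, the tumour necrosis factor gene, rose 6.66-fold (log2 2.74 ± 0.22, adjusted p = 9.01e-05). Of 26 interferon response genes, 25 were higher (26 over the list alone), with a median of 1.95 (camera adjusted p = 1.45e-14, adjusted p = 0.317 with an estimated correlation). Isg15 rose 4.67-fold (log2 2.22 ± 0.26) and Zbp1, a sensor of viral nucleic acid, 5.41-fold (2.44 ± 0.26). Without WT DSS 1 the interferon response count was 15 and the median 1.24. Of 17 antimicrobial and mucosal defence genes, 12 were higher and 3 lower (median 2.43, camera adjusted p = 7.92e-06, adjusted p = 0.0634 with an estimated correlation). Duox2, the epithelial peroxide-producing oxidase, rose 5.40-fold (log2 2.43 ± 0.14). Ang4, a bactericidal ribonuclease with near-identical gene copies, fell by 4.27 (SE 0.52), a value uncertain where reads were divided between copies.

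Of 21 unfolded protein response genes, 11 were higher and 3 lower (median 0.63, camera adjusted p = 0.003, adjusted p = 0.317 with an estimated correlation). Creld2 rose 2.71-fold (log2 1.44 ± 0.13) and Calr, the chaperone calreticulin, 2.75-fold (1.46 ± 0.14). The lower count of this unfolded protein response list was 1 without WT untreated 1, WT untreated 2 or WT DSS 2. Of 24 proliferation genes, 21 were higher (24 over the list alone), with a median of 1.46 (camera adjusted p = 1.08e-08, adjusted p = 0.375 with an estimated correlation). The size of this shift and the number of passing genes depended on WT DSS 2, but the direction did not. The proliferation median was 0.62 without it, and the median difference from untreated WT was 0.63 in WT DSS 1 and 1.95 in WT DSS 2. Without WT untreated 1, 2 and 3 the count was 9, 9 and 11. Of 24 colonocytes markers, 11 were lower and 1 higher (over the list alone 13 and 2), with a median of -0.51 (camera adjusted p = 0.00017, adjusted p = 0.317 with an estimated correlation). Aqp8, a colonic water channel, fell by 1.55 (SE 0.22), and Slc20a1, a phosphate transporter, fell by 2.16 (SE 0.26). Without WT DSS 2, 7 of the colonocytes genes were lower, and the 1 higher gene no longer passed without WT untreated 2 or 3.

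Of 16 circadian clock genes, 10 were lower and 4 higher (median -1.71, camera adjusted p = 0.000352, adjusted p = 0.195 with an estimated correlation), and the higher count was 2 without WT untreated 3 or WT DSS 1. Of 15 T cells markers, 11 were lower (14 over the list alone), with a median of -1.73 (camera adjusted p = 3.05e-06, adjusted p = 0.375 with an estimated correlation). Zap70, a T cell receptor kinase, fell by 2.18 (SE 0.42, adjusted p = 0.00754), but adjusted p was 0.0771 without WT DSS 2. The T cells count was 6 without WT untreated 2. Without WT DSS 2 it was 0 by the edgeR quasi-likelihood test (11 lower at unadjusted p under 0.05, while DESeq2 was not run without that library). The 36 collagens and matrix proteins did not shift as a group (2 higher and 2 lower, median -0.27, camera adjusted p = 0.483), and the collagens and matrix proteins median was -0.42 without WT untreated 1, -0.61 without WT DSS 1 and -0.08 without WT DSS 2. Fn1 fell by 1.3 (SE 0.38, adjusted p = 0.0381), a call that ended without WT untreated 1 (0.076), WT untreated 3 (0.107), WT DSS 1 (0.13), WT DSS 2 (0.177), TG DSS 1 (0.0561) or TG DSS 2 (0.0563). Itgb6 rose 1.57-fold (log2 0.65 ± 0.15, adjusted p = 0.0164), lost without WT untreated 2 (0.0525), WT untreated 3 (0.0648) or WT DSS 1 (0.0927). In all, 2788 genes differed (1434 higher, 1354 lower). The split was 1146 and 1700 under total count scaling, and 990 and 1573, 956 and 1562, and 918 and 1496 in the 3 FPKM fits. The number was 1515, 1501 and 1519 without WT untreated 1, 2 and 3, and 970 without WT DSS 2, while 88 of the 132 named genes passed in every fit. X-linked genes were not over-represented (64 of 437 against 2712 of 13604 others), which does not separate sex from treatment.

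In TG tissue, inflammatory genes were higher after DSS, and Fn1 and Pla2g4c, which were higher in untreated TG than in untreated WT, were lower. Slpi rose 64.8-fold (log2 6.02 ± 0.34, SE, adjusted p = 1.58e-05), from 1.58 ± 0.557 CPM (SD, n = 3) to 103 ± 36.2 CPM (n = 2). Clca4b rose 110-fold (log2 6.78 ± 0.45, adjusted p = 4.24e-05), from 9.96 ± 4 to 1095 ± 354 CPM, and Il1b rose 14.6-fold (log2 3.87 ± 0.36, adjusted p = 0.000324), from 0.824 ± 0.354 to 12.2 ± 3.28 CPM. Fn1 fell by 4.72 (SE 0.42, adjusted p = 0.000214), from 38.7 ± 12.9 to 1.46 ± 0.249 CPM. Pla2g4c fell by 7.58 (SE 0.36, adjusted p = 5.22e-06), from 337 ± 46.7 to 1.76 ± 0.249 CPM. In all 5, both DSS libraries lay beyond all 3 untreated libraries, again a condition for naming among the largest rises and falls. Itln1, a carbohydrate-binding mucosal lectin, fell by 5.17 (SE 0.48). Nos2, the inducible nitric oxide synthase, rose 13.8-fold (log2 3.79 ± 0.44), and Tac1, the substance P precursor of enteroendocrine cells and neurons, 12.7-fold (3.67 ± 0.25).

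Of 11 neutrophils markers, 9 were higher (10 over the list alone), with a median of 3.45 (camera adjusted p = 6.14e-14, adjusted p = 0.058 with an estimated correlation). On log2 FPKM with a pseudocount of 1 the neutrophils median was 2 (7 genes), and 0.79 without a filter. Ptprc averaged 13.8 ± 3.98 CPM after DSS (n = 2) against 48.5 ± 36 CPM untreated (n = 3), with TG untreated 1 at 8.94 CPM. S100a9 rose 72.2-fold by pooled counts (95% interval 27.8 to 268) and S100a8 rose 26.1-fold (12.3 to 66.1). The neutrophils count was 5 without TG DSS 1 or 2. Of 28 inflammatory cytokines and chemokines, 13 were higher (17 over the list alone), with a median of 1.62 (camera adjusted p = 1.57e-11, adjusted p = 0.212 with an estimated correlation), and the count was 8 without TG DSS 1. In those FPKM fits the inflammatory cytokines and chemokines median was 0.71 (21 genes) and 0.57. Of 36 collagens and matrix proteins, 10 were lower (over the list alone 1 higher and 15 lower), with a median of -1.05 (camera adjusted p = 8.92e-09, adjusted p = 0.373 with an estimated correlation), or -0.46 (15 genes) and -0.30 in those FPKM fits. Col1a1 fell by 2.99 (SE 0.46, adjusted p = 0.0052), from 20.1 ± 8.73 to 2.52 ± 0.33 CPM. Its call ended without TG DSS 1 (0.0689) or TG DSS 2 (0.0664). Of 16 fibroblasts markers, 3 were lower and 1 higher (over the list alone 5 and 1), and 4 lay above 0. As a group the fibroblasts markers shifted down (median -0.89, camera adjusted p = 0.0203, adjusted p = 0.502 with an estimated correlation). That call ended without TG untreated 2 (0.0903, fibroblasts median -0.48) or TG untreated 3 (0.051), and the fibroblasts median was -0.30 in the unfiltered FPKM fit. The lower count of fibroblasts was 7 without TG untreated 1, 1 without TG DSS 2, and 0 without TG DSS 1 by edgeR (5 lower at unadjusted p under 0.05, while DESeq2 was not run without that library). The higher gene, Il11 (1.56, adjusted p = 0.0489), was lost in 8 fits: without WT untreated 1 (0.0746), 2 (0.0671) or 3 (0.0824), TG untreated 1 (0.063), 2 (0.0728) or 3 (0.109), or TG DSS 1 (0.224) or 2 (0.209), and another of the fibroblasts markers was higher without WT untreated 2. The collagens and matrix proteins count was 19 without TG untreated 1, 5 without TG untreated 2 or 3, and 1 without TG DSS 1 or 2.

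Of 14 intestinal stem cells markers, 3 were lower (5 over the list alone), with a median of -0.59 (camera adjusted p = 0.000431, adjusted p = 0.212 with an estimated correlation). Axin2, a Wnt target, fell by 1.46 (SE 0.13, adjusted p = 0.000294), as it had in WT (fell by 1.39, SE 0.13, adjusted p = 0.000192). Of 17 enteroendocrine cells markers, 5 were higher (8 over the list alone), with a median of 0.56 (camera adjusted p = 0.000146, adjusted p = 0.389 with an estimated correlation). Pyy, the peptide YY hormone gene, rose 3.64-fold (log2 1.86 ± 0.20, adjusted p = 0.000656). Without TG DSS 1 the enteroendocrine cells count was 1 and the median 0.37, and without TG DSS 2 the count was 3. The 26 interferon response genes did not pass as a group (median -0.63, camera adjusted p = 0.119) but did without WT DSS 1 (0.0129) or WT DSS 2 (0.0145). The 21 unfolded protein response genes did not pass (median -0.22, camera adjusted p = 0.0577) but did without WT untreated 1 (0.0354), WT DSS 1 (0.0486), WT DSS 2 (0.0483) or TG DSS 2 (0.0164), and the unfolded protein response median was -0.14 without TG untreated 2 or TG DSS 1. Itgb6 rose 1.55-fold (log2 0.63 ± 0.15, adjusted p = 0.0399), lost without WT untreated 1 (0.072), WT untreated 2 (0.0666), WT untreated 3 (0.069), TG untreated 2 (0.0881), TG untreated 3 (0.0599), TG DSS 1 (0.145) or TG DSS 2 (0.278). In all, 771 genes differed (468 higher, 303 lower, or 413 and 402 under total count scaling). The number was 1677 (774 higher, 903 lower) without TG untreated 1, 425 without TG untreated 3, 241 without TG DSS 1 and 173 without TG DSS 2, while 35 of the 96 named genes passed in every fit. Sex changed here too, and 15 of 437 X-linked genes passed against 748 of 13604 others.

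**Figure D3:**
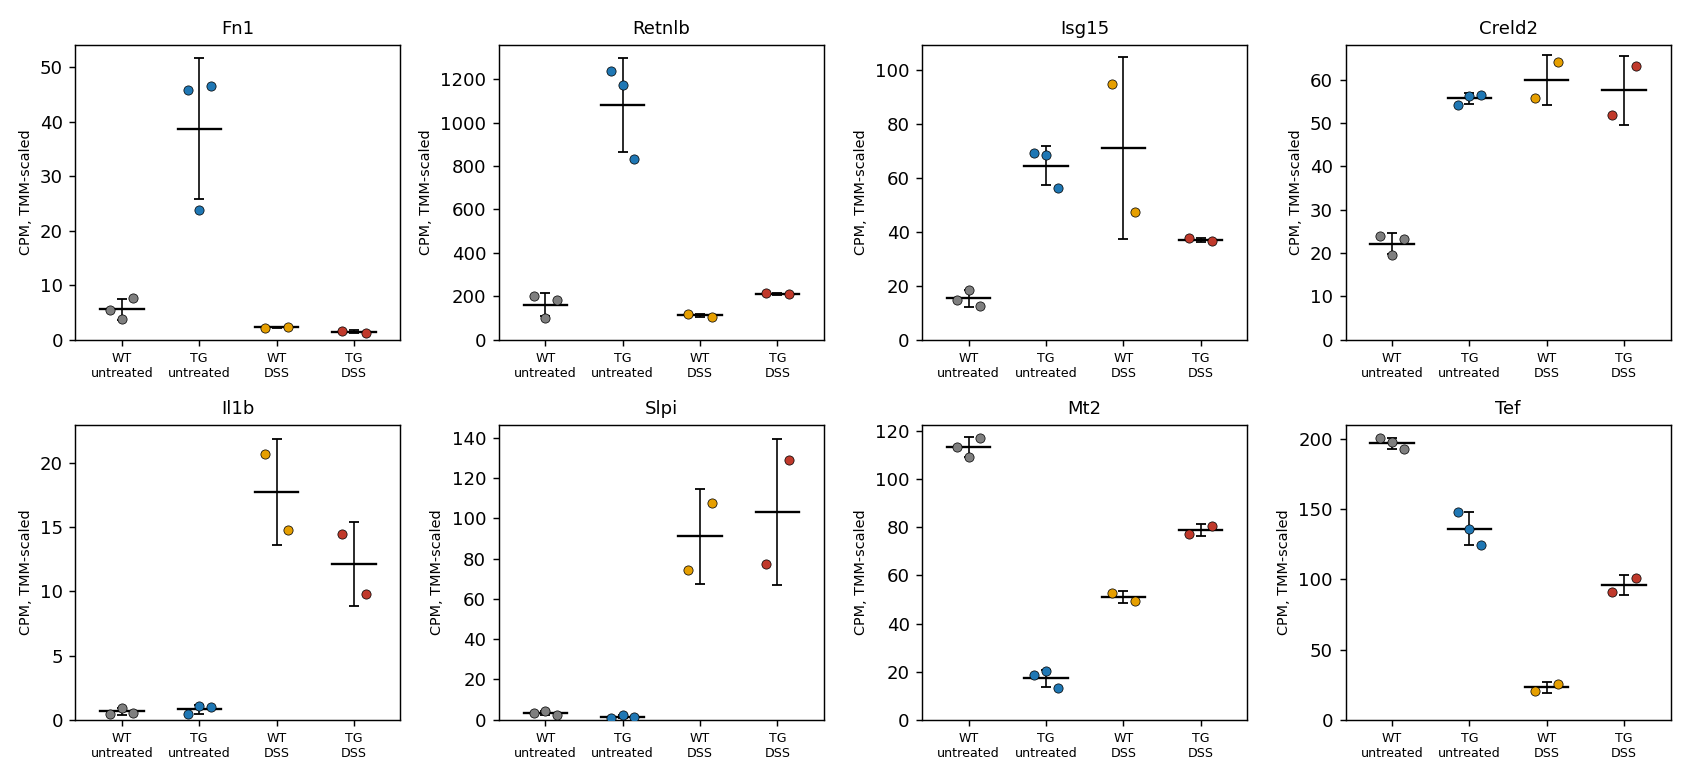
Expression of Fn1, Retnlb, Isg15, Creld2, Il1b, Slpi, Mt2 and Tef in TMM-scaled CPM (vertical axes), 1 point per library, bars at the group mean and error bars of 1 SD (n = 3, 3, 2 and 2). Fn1 averages 38.7 CPM in untreated TG and 1.46 CPM in TG after DSS.

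After DSS, TG and WT differed in few genes, with the clock output genes Tef and Dbp among them. Tef was 4.16-fold higher in TG (log2 2.06 ± 0.15, SE, adjusted p = 0.000348), at 95.9 ± 7.28 CPM (SD, n = 2) against 23.0 ± 3.85 CPM (n = 2). Dbp was 8.46-fold higher (log2 3.08 ± 0.30, adjusted p = 0.0032), at 33.5 ± 13.4 against 3.96 ± 0.411 CPM. Of the 26 genes that passed, 14 were named and followed through the fits without a library. Of the 14, only Tef, Dbp and the transgene passed in every fit. For Tef and Dbp each TG library lay above each WT library, as the naming rule required of the largest rises and falls. Cyp4b1 was also higher (log2 2.43 ± 0.36, adjusted p = 0.0374), at 16.1 ± 2.06 against 3 ± 1.03 CPM. Its call ended without WT untreated 1 (0.0837), WT untreated 3 (0.0909), TG untreated 2 (0.0749), TG untreated 3 (0.0676), WT DSS 2 (0.143), TG DSS 1 (0.16) or TG DSS 2 (0.231). Of 16 circadian clock genes, 6 were higher (over the list alone 9 higher and 2 lower), with a median of 0.83 (camera adjusted p = 1.35e-05, adjusted p = 0.38 with an estimated correlation). The circadian clock count was 3, 2 and 3 without WT untreated 1, 2 and 3, and 2 without TG untreated 2, TG untreated 3, WT DSS 2, TG DSS 1 or TG DSS 2. Without TG untreated 1, 2 of these genes were also lower.

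Of 26 interferon response genes, 0 passed singly by the edgeR quasi-likelihood test (16 lower at unadjusted p under 0.05, 4 lower by DESeq2, 14 lower over the list alone). Together they were lower in TG, with a median of -0.89 (camera adjusted p = 1.12e-10, adjusted p = 0.427 with an estimated correlation). The interferon response median was -0.33 without WT DSS 1, and 1 and 3 genes were lower without TG untreated 1 and WT DSS 2. Of 24 colonocytes markers, 0 passed singly by the same test (13 higher at unadjusted p under 0.05, 6 higher by DESeq2, 12 higher over the list alone). As a group they were higher, with a median of 0.53 (camera adjusted p = 1.22e-08, adjusted p = 0.384 with an estimated correlation), and 4 and 5 colonocytes genes were higher without TG untreated 1 and WT DSS 1. Of 28 inflammatory cytokines and chemokines, 0 passed singly by the same test (4 higher and 7 lower at unadjusted p under 0.05, 1 higher and 1 lower by DESeq2, 2 higher and 2 lower over the list alone). As a group the inflammatory cytokines and chemokines were lower in TG, with 4 of 28 above 0 and a median of -0.67 (camera adjusted p = 0.00125, adjusted p = 0.483 with an estimated correlation), a call that ended without WT DSS 1 (0.0764), where 1 gene was lower. Of 15 goblet cells markers, only the secretory lineage factor Atoh1 was higher (4 over the list alone), while all were above 0, with a median of 0.77 (camera adjusted p = 6.61e-07, adjusted p = 0.427 with an estimated correlation), or 0.45 without WT DSS 2. Atoh1 (log2 0.93, adjusted p = 0.0374) was lost without WT untreated 1 (0.0837), WT untreated 2 (0.0728), WT untreated 3 (0.0909), TG untreated 2 (0.0683), WT DSS 2 (0.128), TG DSS 1 (0.225) or TG DSS 2 (0.231).

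The 6 erythrocytes markers had the largest median of the lists in this comparison, 3.54 (camera adjusted p = 3e-07, adjusted p = 0.411 with an estimated correlation). Their median difference from untreated WT was -3.91 and -4.43 in the WT DSS libraries and -0.12 and -1.71 in the TG DSS libraries, so erythrocyte transcripts lay less far below untreated WT in TG. Single haemoglobin genes have near-identical copies, and their values are uncertain. Of the 6, 3 passed singly (5 over the list alone). The erythrocytes count was 1 without WT DSS 1, and by edgeR 0 without WT untreated 1, 2 or 3 or TG untreated 2 or 3 (5 at unadjusted p under 0.05 in each) and 0 without WT DSS 2 or TG DSS 1 (4 in each), while DESeq2, not run without a library, gave 4. The 36 collagens and matrix proteins did not pass (median -0.07, camera adjusted p = 0.62) except without WT DSS 2 (0.0433), and the collagens and matrix proteins median was 0.19 without WT DSS 1, -0.18 without WT DSS 2 and -0.19 without TG DSS 2. The 21 unfolded protein response genes did not pass (median -0.01, mean 0.02, camera adjusted p = 0.847), and the unfolded protein response median ranged from -0.11 without TG DSS 2 to 0.08 without TG DSS 1. Fn1 read 2.25 ± 0.0964 CPM in WT and 1.46 ± 0.249 CPM in TG (log2 fold change -0.62 ± 0.46, adjusted p = 0.663). In all, 26 genes differed (25 higher, 1 lower). The split was 6 and 1 under total count scaling, 7 and 2, 7 and 1, and 6 and 6 in the 3 FPKM fits, and 9 and 11 without WT DSS 2. The number was 7, 10 and 8 without WT untreated 1, 2 and 3, 145, 8 and 13 without TG untreated 1, 2 and 3, 134 without WT DSS 1, and 4 and 7 without TG DSS 1 and 2.

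Whether the DSS response differed between the genotypes was asked with the interaction, the log2 change with DSS in TG minus that in WT. Mt2 had opposite changes in the 2 genotypes by group mean (interaction 3.34 ± 0.22, SE, adjusted p = 0.000227), from 113 ± 4.12 to 51.0 ± 2.44 CPM in WT and from 17.3 ± 3.55 to 78.9 ± 2.57 CPM in TG (n = 3 and 2 in each genotype). Cyp4b1 did so as well (5.52 ± 0.46, adjusted p = 0.000879), from 51.4 ± 16.1 to 3 ± 1.03 CPM in WT and from 6.05 ± 1.37 to 16.1 ± 2.06 CPM in TG. Pla2g4c dropped further in TG (-4.18 ± 0.44, adjusted p = 0.00252). Bst2 went from 13.3 ± 0.473 to 55.4 ± 11.1 CPM in WT and from 45.4 ± 6.6 to 26.6 ± 6.61 CPM in TG (-2.82 ± 0.27, adjusted p = 0.00161). The clock genes Tef (2.59 ± 0.18, adjusted p = 0.000227), Dbp (3.90 ± 0.36, adjusted p = 0.00161), Per3 (2.25 ± 0.22, adjusted p = 0.00175) and Cry2 (1.86 ± 0.20, adjusted p = 0.00269) had lower means after DSS in WT and less or no such drop in TG. Sstr1, a somatostatin receptor gene (2.93 ± 0.28, adjusted p = 0.00161), and Slc2a5, the fructose transporter gene (2.08 ± 0.26, adjusted p = 0.00734), also had positive interactions. The untreated TG level of several of these genes already differed from WT, so an interaction can come from the starting level as well as from the response.

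Of 26 interferon response genes, 12 had negative interactions (21 over the list alone), with a median of -2.07 (camera adjusted p = 1.64e-22, adjusted p = 0.228 with an estimated correlation). The interferon response count was 3 without WT untreated 1, WT untreated 3 or TG untreated 2, 4 without TG untreated 3, and 1 without TG DSS 1 or TG DSS 2. The 17 antimicrobial and mucosal defence genes shifted down (median -1.82, camera adjusted p = 4.88e-09, adjusted p = 0.0379 with an estimated correlation), with a median of -1.03 on log2 FPKM with a pseudocount of 1. Of 21 unfolded protein response genes, 6 had negative interactions (over the list alone 10 negative and 1 positive), with a median of -0.88 (camera adjusted p = 6.55e-10, adjusted p = 0.0941 with an estimated correlation). The unfolded protein response count was 1, 3 and 2 without WT untreated 1, 2 and 3, 3 without TG untreated 2, TG untreated 3, WT DSS 2 or TG DSS 2, and 0 without TG DSS 1 by edgeR (10 at unadjusted p under 0.05, while DESeq2 was not run without that library). Of 24 colonocytes markers, 5 had positive interactions (15 over the list alone), with a median of 1.2 (camera adjusted p = 3.36e-12, adjusted p = 0.0941 with an estimated correlation). The colonocytes count was 2 without WT untreated 1, TG untreated 2, TG untreated 3 or TG DSS 2, 3 without WT untreated 3 or WT DSS 2, 10 without WT DSS 1, and 0 without TG DSS 1 by edgeR (14 at unadjusted p under 0.05).

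Of 16 circadian clock genes, 8 had positive interactions (over the list alone 9 positive and 3 negative), with a median of 1.44 (camera adjusted p = 9.12e-06, adjusted p = 0.0941 with an estimated correlation), and the count was 5 without TG untreated 3, WT DSS 2, TG DSS 1 or TG DSS 2. Of 28 inflammatory cytokines and chemokines, only the acute phase gene Saa1 passed singly, with a positive interaction (1.33, adjusted p = 0.0406), while over the list alone 3 were positive and 4 negative. Saa1 was lost without WT untreated 1 (0.114), WT untreated 2 (0.091), WT untreated 3 (0.0718), TG untreated 2 (0.0862), TG untreated 3 (0.0907), WT DSS 1 (0.0563), TG DSS 1 (0.0954) or TG DSS 2 (0.17), and 2 genes of the list were negative without TG untreated 1. As a group, with 8 of 28 above 0, the list shifted down (median -0.65, camera adjusted p = 0.0393, adjusted p = 0.648 with an estimated correlation). That call ended without WT untreated 1 (0.0948), TG untreated 1 (0.0557), TG untreated 3 (0.0682) or WT DSS 1 (0.224), and the inflammatory cytokines and chemokines median was -1.06 without WT untreated 2, -0.99 without TG untreated 1, -0.21 without TG untreated 2 and -0.42 on unfiltered log2 FPKM with a pseudocount of 1. Of 11 neutrophils markers, only Ly6g, a granulocyte surface antigen gene, passed singly, also with a positive interaction (1.89, adjusted p = 0.0205), and over the list alone 1 was positive and 1 negative. Ly6g was lost without WT untreated 1 (0.0514), WT untreated 3 (0.0614), TG untreated 3 (0.0557) or TG DSS 2 (0.0917). The group shifted the other way, with 2 of 11 above 0 (median -0.53, camera adjusted p = 0.0285, adjusted p = 0.435 with an estimated correlation). The neutrophils call ended without WT untreated 3 (0.0538, median -0.31), TG untreated 1 (0.052, median -0.90), WT DSS 1 (0.224, median -0.35) or TG DSS 2 (0.285), and the median was -1.22 without WT untreated 2, -1.09 without TG DSS 1, and -0.17 (7 genes) and -0.21 (no filter) on log2 FPKM with a pseudocount of 1. The 36 collagens and matrix proteins shifted down (median -0.96, camera adjusted p = 3.09e-07, adjusted p = 0.402 with an estimated correlation, median -0.24 in that unfiltered FPKM fit), with Fn1 alone passing singly (-3.42 ± 0.55, adjusted p = 0.0238). The Fn1 interaction ended without WT untreated 1 (0.0743), TG untreated 3 (0.0598), WT DSS 2 (0.0783), TG DSS 1 (0.129) or TG DSS 2 (0.133). Of all 14072 genes, 119 passed (74 positive, 45 negative), 12 of the 42 named in every fit. The number was 35, 63 and 41 without WT untreated 1, 2 and 3, 385, 56 and 41 without TG untreated 1, 2 and 3, 424 without WT DSS 1, 24 and 34 without TG DSS 1 and 2, and 101 (37 positive, 64 negative) without WT DSS 2. The DSS responses of WT and TG shared 533 genes, 315 higher in both (47.7 expected by chance if independent) and 199 lower in both (29.2 expected), with 19 opposite. Across all tested genes, which are not independent, the 2 responses correlated at 0.66. The TG differences before and after DSS shared 10 genes, 8 of them opposite in sign, and correlated at 0.17 across genes.

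**Figure D4:**
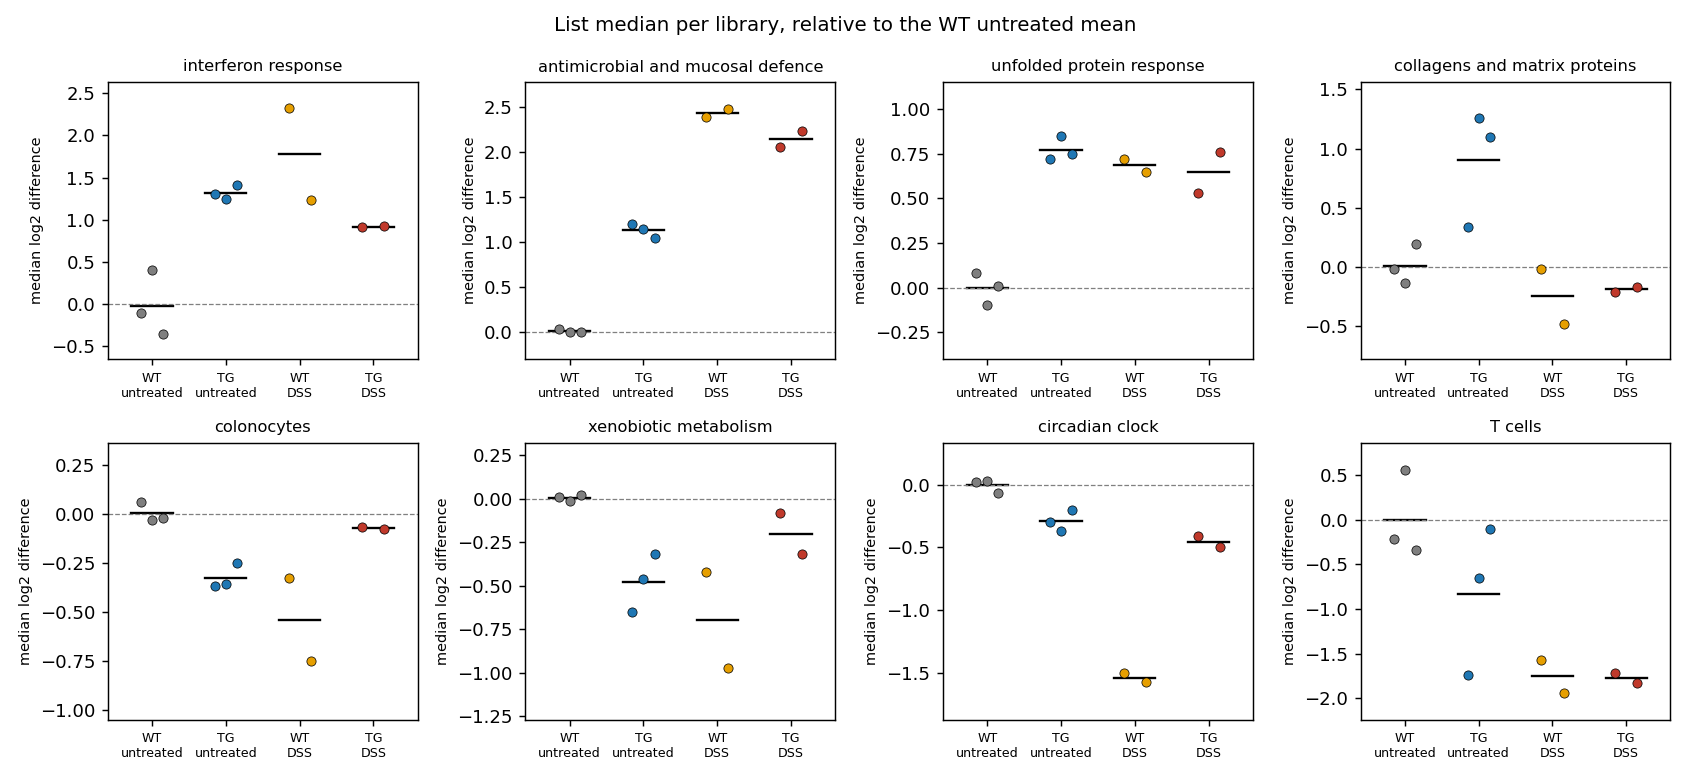
Median log2 difference from the mean of untreated WT (vertical axis) for 8 gene groups, 1 point per library and bars at the group mean (n = 3, 3, 2 and 2). The interferon response genes stand at 1.31, 1.25 and 1.41 in the 3 untreated TG libraries and at 2.33 and 1.23 in the 2 WT DSS libraries.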

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

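The tests of sex, of time of day and of goblet cell products below were chosen only after the results they bear on had been seen. The difference between the TG effect in untreated tissue and after DSS was tested directly as the interaction, and 119 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg). Interactions were positive for Cyp4b1 (5.52), Dbp (3.90), Mt2 (3.34), Tef (2.59) and Per3 (2.25) on the log2 scale, each passing in all 10 fits without a library. Car4, a colonic carbonic anhydrase gene (1.68, adjusted p = 0.00776), passed in all but the fit without TG DSS 1 (0.0507). They were negative for Pla2g4c (-4.18) and Bst2 (-2.82), which passed in all 10 fits, Isg15 (-3.02), the interferon-induced protease gene Usp18 (-3.61), Fn1 (-3.42), Creld2 (-1.39) and Hyou1 (-1.26). Isg15 was lost without TG DSS 1 (0.0598) or TG DSS 2 (0.0565), Creld2 without TG DSS 1 (0.0928), and Hyou1 without WT untreated 1 (0.0572) or TG DSS 1 (0.124). Usp18 was lost without WT untreated 1 (0.0653), WT untreated 3 (0.0648), TG untreated 2 (0.0508), TG DSS 1 (0.132) or TG DSS 2 (0.109). Fn1 was lost without WT untreated 1 (0.0743), TG untreated 3 (0.0598), WT DSS 2 (0.0783), TG DSS 1 (0.129) or TG DSS 2 (0.133).

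As groups, the interferon response (median -2.07), antimicrobial and mucosal defence (-1.82), collagens and matrix proteins (-0.96) and unfolded protein response (-0.88) had negative interactions. The circadian clock (1.44), colonocytes (1.2) and xenobiotic metabolism (0.78, camera adjusted p = 1.64e-12, adjusted p = 0.16 with an estimated correlation) had positive ones. Each of the 7 kept its direction under the 6 other scalings, but on log2 FPKM with a pseudocount of 1 the median of antimicrobial and mucosal defence was -1.03, and without a filter that of collagens and matrix proteins was -0.24. With an estimated correlation only the antimicrobial and mucosal defence genes passed (adjusted p = 0.0379). The untreated TG effect that enters each interaction was also compared with other splits of the 6 untreated libraries. Of the 10 splits into 3 and 3, 1 split, the real one, gave 520 genes, and the highest other gave 1. For gene groups, 1 split, again the real one, gave 18, and the others gave 8 to 17. Camera with the preset correlation thus passed many groups in mixed splits. Each mixed split still held 2 libraries of 1 genotype and 1 of the other on each side. It kept part of the genotype difference and put the rest into the spread within groups. The splits therefore cannot show how many genes or groups pass without a genotype difference. The number of passing groups does not by itself speak for genotype. The splits are too few for a share under 0.05.

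Sex and DSS cannot be told apart in these data. Of the 10 libraries, 0 carry Xist and Kdm5d levels that depart from the treatment, since the 6 untreated libraries carry Kdm5d transcripts and the 4 DSS libraries carry Xist, so a model with both terms could not be fitted. Sex of the animals in place of DSS, DSS itself, or both are open explanations for any DSS effect outside the X and Y chromosomes. The comparisons of TG with WT were each made within 1 sex, but the interaction may reflect either a treatment or a sex difference in the TG effect.

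The clock output genes were higher in TG than in WT after DSS, and collection at another time of day is a candidate explanation. A shift in phase should move genes that peak opposite to Dbp and Tef the other way, and Arntl, Npas2, Clock, Nfil3 and Cry1 had a median log2 fold change of -0.87, with Cry1 not lower (0.13, SE 0.16) and single adjusted p-values from 0.101 to 0.809. The median of Dbp, Tef, Per3, Ciart, Per2 and Cry2 was 1.72 over all libraries and 1.55 in the lowest of the 4 fits without a DSS library. Each of these genes had passed in this same comparison, so their median cannot decide whether a single library was the source. The circadian clock list was written before the data were examined. Its median difference from untreated WT was -1.5 and -1.57 in the WT DSS libraries and -0.41 and -0.5 in the TG DSS libraries. For the list as a whole, these values argue against a single library as the source. An effect of the transgene on the clock under DSS stays open as well, because collection times are not given in the labels. With 2 libraries in each DSS group, the phase values carry standard errors of 0.16 to 0.39. Time of day is also open for DSS against untreated in WT, and so for the clock interactions. There Dbp (-4.72) and Tef (-3.09) were lower after DSS. Arntl (1.82), Npas2 (1.86), Nfil3 (1.41) and Cry1 (0.52) were higher, while Clock did not pass (0.27).

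The unfolded protein response genes were higher in untreated TG, beside higher goblet cell and interferon genes. The tables argue against TG untreated 1, the library that stood apart from its group, as the source, since 13 genes of the group were higher without it, while the unfolded protein response count was 8, 6 and 5 without WT untreated 1, 2 and 3 and 7 and 10 without TG untreated 2 and 3. A larger share of goblet cells stays open. Paneth cells markers were also higher in untreated TG (median 1.95), and a larger share of Paneth cells was not tested. The goblet products Muc2 (0.57), Fcgbp (1.19), Zg16 (-0.14), Clca1 (1.73) and Tff3 (0.1) had a median log2 fold change of 0.57, which is -0.17 relative to the group. None passed singly (edgeR adjusted p from 0.0634 to 0.858). The standard error of the mean over these products was 0.35, which leaves out the spread of the group itself. Goblet markers were also higher in TG after DSS (median 0.77), where the unfolded protein response genes did not pass as a group (median -0.01, camera adjusted p = 0.847), but those genes already stood above untreated WT in both DSS groups (0.72 and 0.65 in WT, 0.53 and 0.76 in TG). Stress from folding a highly expressed transgene product is a biological explanation that may apply, and no test here separates it from a change in cell composition.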

How the results depend on the processing

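Leaving out the genes of the X and Y chromosomes was chosen only after the data had been seen, and the other alternatives were fixed before. Under DESeq2 size factors, upper quartile scaling, both other low-count filters, robust empirical Bayes and without X and Y genes, no gene count moved by more than 1.5 times. Of the named genes, 363 of 364, 361 of 364, 357 of 364, 324 of 326, 361 of 364 and 353 of 353 kept direction and side of the threshold. DESeq2 gave more genes: 1041 for TG against WT untreated, 258 for TG against WT after DSS, 1244 for DSS in TG and 430 for the interaction, with 360 of 363 named genes the same. Total count scaling gave 7 genes for TG against WT after DSS, and the 3 FPKM fits (pseudocount 1, 0.1, and 1 without a filter) gave 9, 8 and 12. Of the named genes, 346 of 364 stayed the same under total count scaling, and 304 of 336, 305 of 336 and 297 of 364 in the FPKM fits. The cause was not tested. Fitting only the groups compared gave 8 genes for TG against WT after DSS and 395 for DSS in TG, with fewer samples to estimate the spread. As a replicate block, the replicate number took 2 residual degrees of freedom and gave 166, 7, 1614, 356 and 41 genes in the 5 contrasts, with 276 of 364 named genes the same.

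Among the genes followed throughout, Itgb6 lost its DSS rise in WT with the replicate block (0.66). It lost its rise in TG when only the groups compared were fitted (0.62), with the replicate block (0.65) and in the FPKM fits (0.47, 0.57 and 0.47). Human ITGB6 no longer passed for DSS in WT with a pseudocount of 1 (0.22 with and without a filter), a value set by the pseudocount at such low levels, or for DSS in TG with the replicate block (-0.68). Values near 0 changed sign: the Itgb6 interaction (0.00 with log2(FPKM + 0.1)), Tgfb1 in untreated tissue (-0.05 under total count scaling and -0.02 in all 3 FPKM fits) and Col3a1 for DSS in WT (0.18 with the replicate block). The cause was not tested. Camera with an estimated correlation gave 1, 0, 0, 0 and 1 gene lists in the 5 contrasts (2, 3, 5, 5 and 9 before adjustment). Fry gave 9 for TG against WT untreated, 3 for TG against WT after DSS and 9 for the interaction.

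Depending on which library was left out, 262 to 357 of 364 named genes stayed the same. Where 1 sample is left in a group, that sample is assumed to vary like the other groups. Gene counts ranged from 58 (without WT untreated 3) to 730 (without TG untreated 1) for TG against WT untreated, and from 4 (without TG DSS 1) to 145 (without TG untreated 1) after DSS. They ranged from 970 (without WT DSS 2) to 4112 (without TG untreated 1) for DSS in WT, from 173 (without TG DSS 2) to 1677 (without TG untreated 1) for DSS in TG, and from 24 (without TG DSS 1) to 424 (without WT DSS 1) for the interaction. The cause of the higher counts without TG untreated 1 was not tested. DSS in WT does not compare that library, so there the cause can lie only in the filter, scaling or spread shared by the fit. Log2 values of Itgb6 ranged from -0.40 to 0.01 for TG against WT after DSS, 0.43 to 0.84 for DSS in WT, 0.55 to 0.71 for DSS in TG and -0.21 to 0.20 for the interaction. Human ITGB6 ranged from -0.79 to -0.63 for DSS in TG. Itgav ranged from -0.25 to 0.03 in untreated tissue and -0.10 to 0.18 for the interaction. Its DSS rise of 1.55-fold in WT (adjusted p = 0.0273) ended without each of the 5 WT libraries in turn, with adjusted p up to 0.116, and its 1.64-fold rise in TG (adjusted p = 0.0384) ended in 7 fits, with adjusted p up to 0.206. Tgfb1 ranged from -0.27 to 0.43 in untreated tissue and -0.28 to 0.42 for the interaction, and Acta2 from -0.96 to 0.13 in untreated tissue and -0.57 to 0.51 for DSS in WT. Col3a1 ranged from -0.14 to 0.03 for TG against WT after DSS and -0.44 to 0.17 for DSS in WT. Acta2 read near 1 CPM or below, which is few counts at a depth of 15393859 to 18284704, and its changes were measured with standard errors of 0.53 to 0.79.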

Other observations

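Nnt, Wdfy1 and the human ITGB6 counts of WT libraries below were looked at only after their values were seen, while the other genes and lists follow the fixed rules. Of 11 heat shock genes, 3 were higher in untreated TG (5 over the list alone), with a median log2 fold change of 0.61 (camera adjusted p = 0.000266, adjusted p = 0.38 with an estimated correlation). Hsph1, a large cytosolic chaperone gene, rose by 2.17 on the log2 scale (adjusted p = 0.00919), a call lost without WT untreated 1 (0.0531) or WT untreated 3 (0.0524). The heat shock count was 1 without WT untreated 1, 5 without TG untreated 1, and 0 without WT untreated 3 by edgeR (5 higher at unadjusted p under 0.05, while DESeq2 was not run without that library). With DSS, the immediate early gene Nr4a1 fell by 1.71 in WT (SE 0.15, adjusted p = 0.000126) and by 1.77 in TG (SE 0.15, adjusted p = 0.000152). Hk2, a hexokinase gene of the hypoxia and glycolysis list, rose 3.56-fold in WT with DSS (log2 1.83 ± 0.17, adjusted p = 0.000186), while that list did not shift as a group (median 0.15, camera adjusted p = 0.382). Angptl4, a lipoprotein lipase inhibitor gene, rose 10.1-fold in TG with DSS (log2 3.34 ± 0.37, adjusted p = 0.000811). Thbs1, the thrombospondin gene, fell by 1.5 in WT (SE 0.24, adjusted p = 0.00316) and by 1.77 in TG (SE 0.24, adjusted p = 0.00275). For each of Nr4a1, Hk2, Angptl4 and Thbs1 the DSS libraries lay beyond the untreated libraries of the same genotype, and each call passed in all 10 fits without a library. Genes that pass in all 10 fits were preferred for this report, so that is not separate support.

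Single libraries differed in 2 genes. Nnt, a mitochondrial transhydrogenase gene, read 70.5 CPM in WT untreated 1 and 13.6 to 21.9 CPM in the other 9 libraries. Wdfy1, an endosomal adaptor gene, read 79.5 CPM in WT DSS 1 and 12.5 to 25.2 CPM elsewhere. The human ITGB6 entry held 12 and 21 counts in the WT DSS libraries and 2 in each untreated WT library, a ratio of 7.78 (95% counting interval 3.22 to 22.7). WT mice lack the transgene and the origin of these counts was not tested, so the ratio does not show that DSS raised the human gene.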
